A study of Halobacterium salinarum NRC-1 with 28 samples.

How the data were processed

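RNA of Halobacterium salinarum NRC-1 strains was compared with a common reference, RNA of the wild type grown at 37 °C, on strand-specific tiling arrays with 2 dyes. The 28 samples came from 9 groups: the Δura3, Δura3ΔtfbD and Δura3ΔtfbE strains at 25 °C, and the Δura3ΔtfbD strain carrying the empty vector, PtfbD-tfbX or PtfbE-tfbX at 25 °C and at 37 °C. The labels spell the third strain Δura3DtfbE, which was read as a deletion of tfbE. These strains are called the Δura3, ΔtfbD, ΔtfbE, vector, PtfbD-tfbX and PtfbE-tfbX strains here. Each group held 1 early, 1 mid and 1 late sample of growth, except the PtfbE-tfbX strain at 25 °C, which held 2 early samples and so 4 in all. The optical densities per the labels ran from 0.196 to 0.874. Replicate numbers in these texts follow increasing optical density within a group. The labels do not say whether the samples of a group came from separate cultures. Every p-value here therefore measures only the spread between these samples, which may be technical. Apart from the 2 early PtfbE-tfbX samples at 25 °C, no group held more than 1 sample of a growth phase. That spread therefore cannot separate variation between cultures or arrays from differences between groups in their change over growth. The SD of a group also holds its change over growth.

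Each sample was hybridized to 2 arrays with the dyes exchanged, so 56 arrays were read, on 7 slides with 8 arrays each and on 4 scan days. Per the file headers, the scanner files were made by Agilent Feature Extraction 10.7.3.1 and hold intensity values for 62976 spots per array, of which 1319 were control spots, together with spot flags. The 61657 other spots carried 61477 distinct probes. The deposited matrix of the authors holds log10 ratios of sample over reference. Its scale and direction were found by comparing each of its columns with the scanner log ratios of the same pair of arrays. The medians of its columns ran from -0.068 to 0.125, and how the authors normalized, centred or filtered it is not given in the sources used here. The order of the dyes on each array was taken from the way the deposited files name their channels together with the dye order in the labels. Culture in rich medium, RNA preparation with a commercial kit, labelling and hybridization were done by the authors, and their further settings are not given in the sources used here.

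Intensities were read in R 4.3.3 with version 1.17.8 of data.table and processed with limma 3.58.1. Local background was removed from the mean signal by the normexp method with an offset of 50. A loess curve was fitted within each array with control spots and outlier spots given no weight. Log2 ratios were turned to sample over reference, spots of the same probe were averaged, and the arrays of a dye-swap pair were averaged. A gene's value was the mean of the probes that lie on its strand, with a median of 9 probes per gene. Of 2674 genes with probes, 2656 passed the filter that a share of at least 0.5 of a gene's probes stood above background in the sample channel in at least 3 samples. These were 2119 genes of the chromosome, 176 of plasmid pNRC100 and 361 of plasmid pNRC200. Of them, 318 share their probe sequences with another place in the genome. Values of such genes cannot be assigned to 1 place. Coordinates count from 1 on the replicons as the array files name them. Python 3.11.15 with numpy 2.4.6 compared the probe sequences and matplotlib 3.10.9 drew the figures.

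Median signal per array ran from 1042 to 3763 in Cy3 and from 222 to 5561 in Cy5. No spot was saturated in any of the arrays used. The arrays with the fewest probes above background in the sample channel were the Cy5 arrays of the late PtfbE-tfbX sample at 25 °C, with 32.4%, and of the late vector sample at 37 °C, with 53.0%. Correlations between the arrays of a dye-swap pair ran from 0.0481 to 0.734 with a median of 0.319, and the lowest correlation between arrays with the sample in the same dye was 0.342 for Cy3 and 0.15 for Cy5. Groups of 3 samples limit precision, and the self-test below gives the size of change that such groups let pass.

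Groups were compared with limma, by a linear model with a term for each group and a term for growth phase, followed by empirical Bayes moderation, with 17 residual and 1.907 prior degrees of freedom. The p-values were adjusted by the Benjamini and Hochberg method over the 2656 genes of each comparison, and a gene was called at an adjusted p under 0.05. Growth phase was tested as late against early in the same model. The comparisons, the model and the settings of the alternatives were fixed before the data were examined, apart from those named as added in the closing text. No paired analysis was possible because the labels give no pairs of cultures, and growth phase entered as a block instead.

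Neighbouring called genes of at least 3 with the same direction were joined into runs. Long segments were sought along each replicon over the probes of both strands as the highest-scoring run, where a probe scored its difference, capped at 1, less 0.25. Only probes with the reference above background in a share of over 0.8 of the arrays entered, and 100 shuffles of the probe order gave the null score. To test the probes outside gene strands, the ends of the segments were found again from gene-strand probes alone. The raised probes of the construct strains were also picked at 37 °C alone and measured at 25 °C. The genes of each replicon were also tested as a set with camera of limma, with its preset correlation between genes and with an estimated one. These replicon sets and the segment search were chosen after the data were seen. The planned named genes could not be used in full, because the reference table pairs none of the array's gene IDs with a name and the files give no names. Gene IDs are therefore printed without names, and the fixed gene lists could not be read. The genes named per comparison were the up to 2 largest rises and 2 largest falls among called genes that had the same direction at each growth phase. For the same reason the deleted genes ura3, tfbD and tfbE could not be found on the arrays, and the strain labels were not checked through them.

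The pipeline was tested on simulated data before use, with 200 of 2674 genes changed. The simulated noise was independent between samples, with no slide, scan day or growth phase by temperature effects. At a log2 change of 1 it recovered 91.0% in the comparison of the ΔtfbD and Δura3 strains with 11 false calls, and 91.5% in the comparison of the PtfbE-tfbX and vector strains at 25 °C with 4 false calls. It recovered 83.5% for the PtfbE-tfbX by temperature interaction with 10 false calls, 88.0% for temperature in the vector strain with 14, and 97.5% for late against early growth with 12. At a log2 change of 0.5 the shares were 63.0%, 63.5%, 39.0%, 65.5% and 83.5% in the same order. A simulated segment of 300 probes lowered by 0.5 was found at its exact ends.

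Alternatives tried were no growth phase term, slide or scan day as a fixed block or as a random block, and a model of only the groups compared. Further ones were each dye alone, no background subtraction, the scanner's own processed signals, median centring in place of loess, the median of a gene's probes, no filter on dim genes and the authors' deposited values. Each sample was also left out in turn. The correlation within slides was 0.119 and within scan days 0.185. Added after the data were seen were a growth phase by temperature term, a fit without the 2 weakest arrays, a fit with 1 gene kept of each shared sequence (89 genes left out), and a fit without the 181 genes of 2 plasmid segments. No array was left out of the comparisons, and the spots of the deposited matrix that are not genes were not tested. The test of growth phase by temperature was repeated in the 3 strains grown at both temperatures, and the named genes of some comparisons were read again with scan day or slide as a block, both chosen after the results were seen, as was the use of scan day or slide as a block in the test of growth phase by temperature.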

Results

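The data collected were 56 tiling arrays of 28 samples, which measured 2656 genes of the chromosome and of the plasmids pNRC100 and pNRC200 in 9 groups of strain and temperature. TFB proteins are general transcription factors that recruit RNA polymerase to promoters. All levels are log2 ratios against wild-type RNA grown at 37 °C, and differences between groups are given with their SE or as group means ± SD. Growth phase spread the samples most: the first principal component held 61.3% of the variance, and the late samples at 25 °C reached scores of 11.1 to 44.6 on it, whereas no other sample passed 4.33.

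To find which transcripts depend on tfbD at 25 °C, the ΔtfbD strain was compared with its Δura3 parent. Transcripts across a stretch of pNRC200 were lower in the deletion strain. A run of 9 genes at 277999 to 286458 had a mean of 0.30 ± 0.05 (SD, n = 3) in the Δura3 strain and -0.97 ± 0.23 (n = 3) in the ΔtfbD strain. The 4 genes at 287533 to 293934 went from 0.15 ± 0.33 to -1.27 ± 0.16, and the 8 genes at 295555 to 300822 from 0.18 ± 0.17 to -1.01 ± 0.14. Among genes with the same direction at each phase, VNG6010G at 4999 to 5394 of pNRC200 was lowest, at -3.88 (SE 0.27) against the Δura3 strain, and its sequence is shared by VNG7008 at the same coordinates of pNRC100. VNG6010G lay at -4.14 to -3.52 in every group built from the ΔtfbD strain, at both temperatures, against -0.23 in the ΔtfbE strain. Whether its fall measures the action of tfbD was not tested.

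Of 2656 genes, 69 passed limma at an adjusted p under 0.05, 13 higher and 56 lower in the ΔtfbD strain, and 59 of them lay on pNRC200. The adjusted p was 1.12e-08 for VNG6010G, and 10 of the higher and 23 of the lower genes changed more than 2-fold. The highest-scoring lowered stretch over probes was 178879 to 307290 of pNRC200 in this comparison, with a median of -0.34, and the highest-scoring raised stretch in the ΔtfbE against the ΔtfbD strain was 263929 to 307290. The shorter segment held 43 of the tested genes, and 31 of these were called, all lower. Outside it, a run of 5 genes at 197023 to 200652 fell by 0.60 on average and a run of 3 genes at 143809 to 147102 by 0.47. In both runs the Δura3 strain stood above all other groups, the ΔtfbE strain included. It lay at 0.55 against -0.11 to 0.12 in the first run and at 0.24 against -0.34 to -0.04 in the other. The 361 pNRC200 genes were lower as a set, with a camera adjusted p = 1.8e-22, and adjusted p = 0.000339 with an estimated correlation. Of the 13 higher genes, 11 share their sequence with other places, and their log2 differences ran from 0.30 to 1.67. The largest, 1.67 (SE 0.32; adjusted p 0.00289) for VNG6391H at 308911 to 309054 of pNRC200 and 1.67 (SE 0.31; adjusted p 0.00236) for VNG6098H at 74803 to 75030, were widest apart late. The late mean of the 11 genes was -1.39 in the Δura3 strain and 0.77 in the ΔtfbD strain. All 6 samples were read on the same scan day, and a fit of that day's samples, which also held 2 ΔtfbE samples, called 74 genes. With slide as a fixed block 34 genes were called, and 35 without the growth phase term.

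Over the probes of both strands, the shorter pNRC200 segment held the deepest part of the fall. Its 526 probes without a copy elsewhere had a median difference of -0.63 between the ΔtfbD and Δura3 strains, against -0.18 on the rest of the plasmid, and 97.1% of them were lower. Probes on the strand of a gene stood at -0.91 and the others at -0.35. The median per sample was 0.01 to 0.17 in the Δura3 strain, -0.04 to 0.19 in the ΔtfbE strain and -0.68 to -0.31 in the ΔtfbD strain. In the strains built from the ΔtfbD strain it was -0.77 to -0.30 in all 19 samples. Of the segment's probe readings, 98.8% and 94.3% lay above background in the Δura3 and ΔtfbE strains, 75.6% in the ΔtfbD strain, and 68.1% to 89.1% in the groups built from it. The segment's coordinates were set on these same data, so these medians describe it and do not test it.

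**Figure D1:**
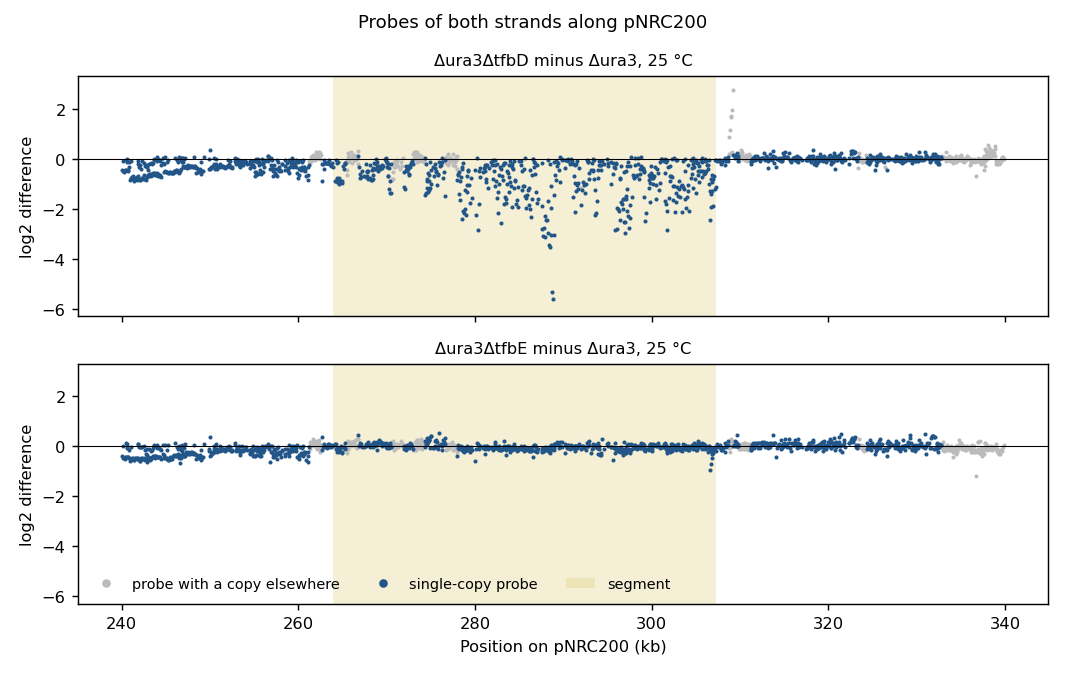
Difference in log2 ratio of each probe (vertical) along pNRC200 on both sides of the segment (horizontal, kb), for the ΔtfbD and ΔtfbE strains each against the Δura3 strain at 25 °C, 3 samples per group. Probes without a copy elsewhere (blue) lie at a median of -0.63 inside the shaded segment in the ΔtfbD strain.

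The same question was put for tfbE with the ΔtfbE strain. Fewer genes differed from the Δura3 strain, and all that passed were lower. The chromosomal gene VNG0053H at 48805 to 49200 went from -1.01 ± 0.32 (SD, n = 3) to -2.62 ± 0.30 (n = 3), a fall of -1.61 (SE 0.18). In all other groups, the ΔtfbD strain included, VNG0053H lay at -2.96 to -2.55, so the Δura3 strain alone stood apart in this gene. Next to each other on the chromosome, VNG0107G at 89209 to 90612 fell by 1.06 (SE 0.15) and its neighbour at 87697 to 89184 by 0.65 (SE 0.09), and VNG0107G lay at -0.54 to -0.24 in all groups but the ΔtfbE strain, where it lay at -1.41 ± 0.16.

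In limma, 7 genes were called, all lower, with adjusted p 6.11e-05 for VNG0053H, for which 53.3% of the probe readings stood above background in the ΔtfbE strain, and 0.000794 for VNG0107G. The other 4 lay on pNRC200 and fell by 0.48 to 0.57. Of these, the genes at 197023 to 197250 and at 197905 to 198384 belong to the run of 5 genes that was also lower in the ΔtfbD strain. That run stood at 0.55 ± 0.09 in the Δura3 strain, -0.04 ± 0.05 in the ΔtfbD strain and 0.12 ± 0.12 in the ΔtfbE strain. The deletions shared 3 lower genes of 56 and 7, against 0.148 for independent lists. Simulated data without effects gave 0, but few genes pass in such data, so this 0 does not test the overlap. The control of 3 samples was too small to be split, so part of this overlap may come from the shared Δura3 samples. The pNRC200 genes were lower as a set (camera adjusted p = 1.67e-09, and adjusted p = 0.0188 with an estimated correlation). With slide as a fixed block no gene was called in limma, and on the scan day that held 2 of the ΔtfbE samples and all Δura3 samples 1 gene was called.

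Whether the deletions differ from each other was tested directly. Compared with the ΔtfbD strain, the ΔtfbE strain had higher transcript levels over the pNRC200 segment, by 1.17 on average for the 9 genes at 277999 to 286458 and by 1.38 for the 4 genes at 287533 to 293934. Levels of these runs in the ΔtfbE strain were 0.20 ± 0.16 and 0.11 ± 0.56 (SD, n = 3). VNG7008 and VNG6010G were higher by 3.71 (SE 0.25) and 3.66 (SE 0.27), and VNG6098H was lower by -1.44 (SE 0.31).

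Of 53 genes called in limma, 35 were higher and 18 lower in the ΔtfbE strain, and 31 of the higher ones lay in the segment. The adjusted p was 2.35e-08 for VNG7008, 2.97e-08 for VNG6010G, 0.0117 for VNG6098H and 0.0172 for VNG6391H, which was lower by -1.41 (SE 0.32). The set of pNRC200 genes passed camera with its preset correlation (adjusted p = 2.64e-06) and did not pass at adjusted p = 0.0735 with an estimated correlation. Within the scan day that held 2 ΔtfbE and all ΔtfbD samples 25 genes were called, and with slide as a fixed block 34 were called.

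The next comparisons asked what tfbX, a synthetic TFB gene, changes when it is carried behind the tfbD promoter in the ΔtfbD strain. At 25 °C the PtfbD-tfbX strain had lower transcript levels than the vector strain over a long part of pNRC100. The 22 genes at 107101 to 132360 stood at 0.00 ± 0.14 (SD, n = 3) with the vector and -1.40 ± 0.05 (n = 3) with PtfbD-tfbX, and the 18 genes at 143935 to 158484 at -0.16 ± 0.12 and -0.99 ± 0.02. VNG7103 at 115123 to 115518 fell from 1.27 ± 1.73 to -4.37 ± 0.08, and VNG7126 at 140869 to 141264 fell by 3.95 (SE 0.25). On the chromosome, VNG0870G at 657553 to 657948 rose from 0.08 ± 0.19 to 0.80 ± 0.14.

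In limma 86 genes were called at 25 °C, 4 higher and 82 lower. The pNRC100 segment from 59851 to 164910 held 55 of the called genes among its 91, and a further 18 lay among 47 genes of pNRC200 that share its sequence. Of the 12 called elsewhere, 4 were higher and 8 lower. The adjusted p was 4.10e-05 for VNG7103 and 6.23e-10 for VNG7126, for which 26.7% of the probe readings stood above background with PtfbD-tfbX, so its fall is uncertain in size. VNG0870G rose by 0.72 (SE 0.07; adjusted p 1.75e-07) and VNG1426H at 1060837 to 1061064 of the chromosome by 0.48 (SE 0.09; adjusted p 0.00200). The pNRC100 genes were lower as a set (camera adjusted p = 9.71e-42, and adjusted p = 4.47e-06 with an estimated correlation). All 6 samples were read on the same scan day, and a fit of these samples alone called 37 genes. The vector samples were all on 1 slide and the PtfbD-tfbX samples all on another, so slide and strain cannot be separated in this comparison. Without the growth phase term 52 genes were called.

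At 37 °C the same region was lower. The 22 genes at 107101 to 132360 stood at 0.10 ± 0.08 (SD, n = 3) with the vector and -1.33 ± 0.02 (n = 3) with PtfbD-tfbX, and the 4 genes at 137803 to 141264 fell by 1.95 on average. VNG7103 fell by 5.02 (SE 0.77) and VNG7126 by 3.74 (SE 0.25), while VNG0870G rose from 0.06 ± 0.17 to 1.17 ± 0.19 and VNG1426H from -0.48 ± 0.12 to 0.40 ± 0.04.

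There 103 genes were called in limma, 15 higher and 88 lower, with 62 in the segment and 18 in its pNRC200 copy. The lists of the temperatures shared 70 of their 82 and 88 lower genes, against 2.72 for independent lists, and 4 of their 4 and 15 higher genes. The adjusted p was 0.000193 for VNG7103, 1.15e-09 for VNG7126 (46.7% of its probe readings above background with PtfbD-tfbX), 2.21e-10 for VNG0870G and 8.58e-07 for VNG1426H, and 1.20e-37 for the pNRC100 genes in camera (adjusted p = 9.06e-06 with an estimated correlation). The samples were spread over scan days, and within the day that held 2 of each strain 27 genes were called. A fit of only the groups compared called 391 genes, and the authors' values gave 50.

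The 552 probes of the pNRC100 segment without a copy elsewhere had a median difference of -0.88 at 25 °C and -0.89 at 37 °C. Probes outside gene strands stood at -0.74 and -0.71, and 97.6% and 95.8% of all 552 were lower. In the PtfbE-tfbX strain the same median was -0.06 at 25 °C. Probes that share their sequence with pNRC200 fell by 0.39 inside the segment at 25 °C and stood at 0.06 outside it. In the PtfbD-tfbX strain 57.4% of the segment's probe readings lay above background at 25 °C, against 98.8% in the vector strain, and 77.4% against 94.3% at 37 °C. On pNRC200 probes without a copy elsewhere and outside the pNRC200 segment, these shares were 85.8% against 91.7% at 25 °C and 96.4% against 90.5% at 37 °C. The 552 probes lie between 112771 and 154074, and the rest of the segment rests on sequence shared with pNRC200, so its fall cannot be assigned to pNRC100. The direct comparison of the constructs gave a segment from 107941 to 163482 at both temperatures.

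**Figure D2:**
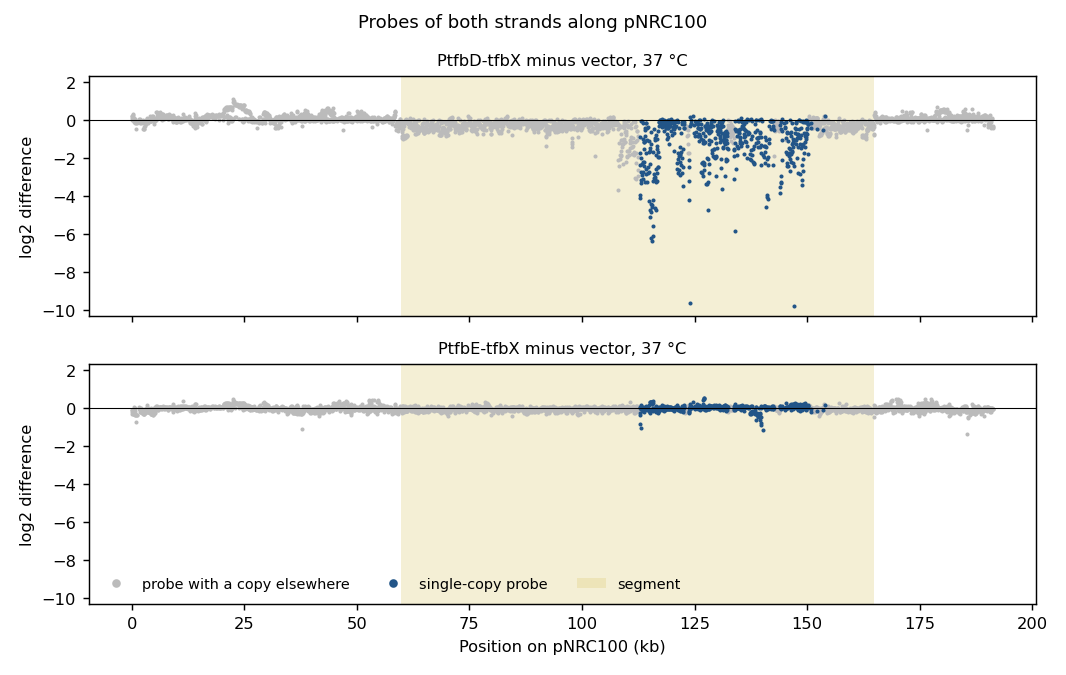
Difference in log2 ratio of each probe (vertical) along pNRC100 (horizontal, kb) at 37 °C, for the PtfbD-tfbX and PtfbE-tfbX strains each against the vector strain, 3 samples per group. Blue probes have no copy elsewhere, and inside the shaded segment they lie at a median of -0.89 with PtfbD-tfbX.

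With tfbX behind the tfbE promoter, few genes were called against the vector strain in the model of all groups. At 25 °C the chromosomal gene VNG1228C at 923119 to 923682 was higher, at -0.01 ± 0.07 (SD, n = 4) against -0.43 ± 0.10 (n = 3). Lower were VNG7124 at 139735 to 140046 of pNRC100, by -0.53 (SE 0.10), and the adjacent pNRC200 genes at 147505 to 151344, by -0.38 (SE 0.05) for VNG6176G and -0.35 (SE 0.05) for its neighbour.

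These 4 genes, 1 higher and 3 lower, were all that limma called at 25 °C, with adjusted p 0.000904 for VNG1228C, 0.0379 for VNG7124 and 0.000904 for VNG6176G. At 37 °C limma also called 4 genes, 1 higher and 3 lower: VNG1228C rose by 0.34 (SE 0.06; adjusted p 0.0367), VNG7124 fell by 0.73 (SE 0.11; adjusted p 0.00280) and VNG6177G by 0.35 (SE 0.05; adjusted p 0.00280). The pNRC100 genes were lower as a set in camera at 37 °C (adjusted p = 2.51e-07, and adjusted p = 0.0188 with an estimated correlation) and at 25 °C (adjusted p = 0.00786), where the call was lost at adjusted p = 0.408 with an estimated correlation. At each temperature the constructs shared 1 higher and 3 lower genes, against 0.00151 and 0.0926 for independent lists at 25 °C. Simulated data without effects gave 0, which does not test this overlap, because few genes pass in such data. The vector samples are the shared control, and the vector strain itself stood apart in VNG1228C, which was lower in it than in the ΔtfbD strain by -0.53 (SE 0.06). VNG7124 stood at 0.60 and 0.54 with the vector at 25 °C and 37 °C, and from -0.72 to 0.18 in the other groups. VNG6176G stood at 0.19 and 0.12 with the vector, and from -0.21 to -0.07 in the other groups. With scan day as a fixed block 41 genes were called at 25 °C and 2 at 37 °C, and with slide as a fixed block none was called in limma at 37 °C. Leaving out replicate 1 of the PtfbE-tfbX strain at 25 °C gave 43 genes. A fit of only the groups compared called no gene at 25 °C but 75 genes at 37 °C, so the count at 37 °C depends on the model.

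A direct comparison asked whether strains with tfbX behind the tfbD or the tfbE promoter differ. The strains also differ over the pNRC100 segment, which may be lost in the PtfbD-tfbX strain. Genes called there or in its pNRC200 copy therefore cannot be assigned to the promoter. Without the genes of the plasmid segments 4 genes were called at 25 °C and 6 at 37 °C. At 25 °C the PtfbE-tfbX strain exceeded the PtfbD-tfbX strain by 2.64 on average over the 5 genes at 114493 to 122364 of pNRC100 and by 0.94 over the 13 genes at 143935 to 155124. VNG7103 was higher by 5.30 (SE 0.72), VNG7126 by 3.74 (SE 0.23), and VNG0870G was lower by -0.77 (SE 0.06). The differences of VNG7126 are uncertain in size, since 26.7% and 46.7% of its probe readings stood above background with PtfbD-tfbX at 25 °C and 37 °C. At 37 °C the 17 genes at 114493 to 132360 were higher by 1.45 on average, VNG7103 by 5.29 (SE 0.77) and VNG7126 by 3.71 (SE 0.25), and VNG0870G was lower by -1.14 (SE 0.07).

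In limma 77 genes were called at 25 °C, 70 higher and 7 lower with PtfbE-tfbX, and 51 of them lay in the pNRC100 segment and 15 in its pNRC200 copy. The adjusted p was 4.49e-05 for VNG7103, 5.59e-10 for VNG7126, 2.56e-08 for VNG0870G and 0.00132 for VNG1427H at 1061173 to 1061316 of the chromosome, which was lower by -0.43 (SE 0.08). At 37 °C 70 genes were called, 58 higher and 12 lower, with 45 in the segment and 10 in the copy. There the adjusted p was 0.000101 for VNG7103, 1.14e-09 for VNG7126, 1.73e-10 for VNG0870G and 5.59e-07 for VNG1426H, lower by -0.91 (SE 0.09). The set of pNRC100 genes was higher in camera at both temperatures (adjusted p = 1.94e-05 and 2.12e-05 with an estimated correlation). No scan day held 2 samples of both strains at the same temperature. Within a day the called genes kept their direction. The median ratio of their difference to that over all days was 0.978 at 25 °C (1 PtfbE-tfbX sample against 3). At 37 °C it was 0.938 (2 against 1) and 1.06 (1 against 2). The samples of a day also entered the full fit, so these ratios are no separate test.

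**Figure D3:**
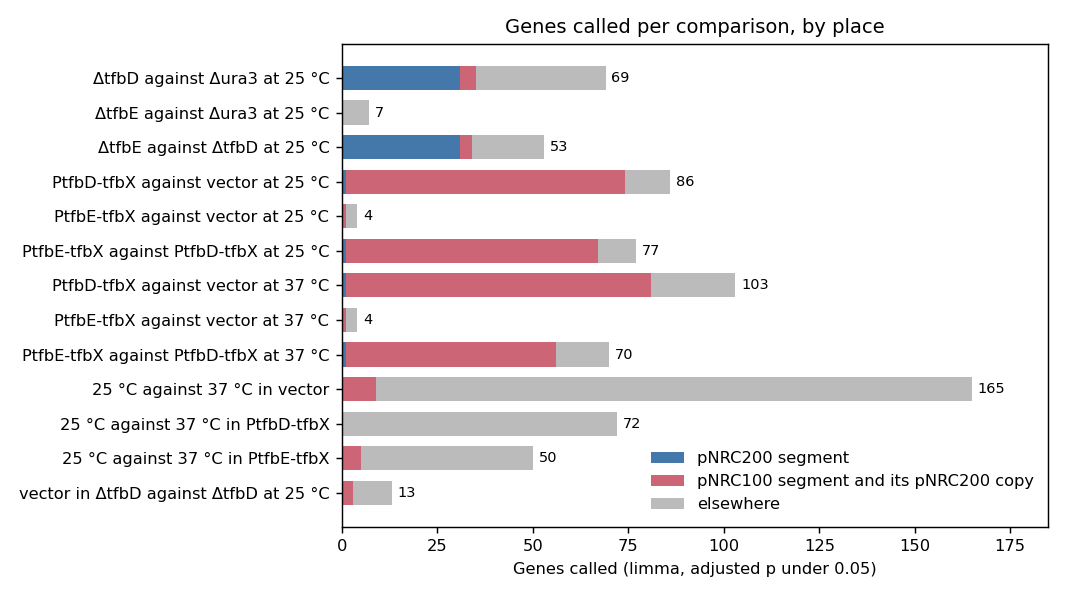
Number of genes called (horizontal) in each of 13 comparisons (vertical), split into the pNRC200 segment, the pNRC100 segment with its pNRC200 copy, and elsewhere; groups held 3 samples, or 4 for PtfbE-tfbX at 25 °C. Of the 103 genes called for PtfbD-tfbX at 37 °C, 22 lay elsewhere.

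Probes at a few places, most of them outside gene strands, rose in the strains that carry a construct. In the PtfbD-tfbX strain 5 probes at 657721 to 657990 of the chromosome, of which 2 belong to VNG0870G and 3 lie on the other strand, averaged 1.70 ± 0.12 (SD, n = 3) at 25 °C, against -0.11 ± 0.14 (n = 3) with the vector. In the PtfbE-tfbX strain 2 probes at 308323 to 308550 of pNRC200 averaged 2.03 ± 0.33 (n = 4), against 0.01 ± 0.06. These probes were picked because they were raised by at least 1 at both temperatures.

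**Figure D4:**
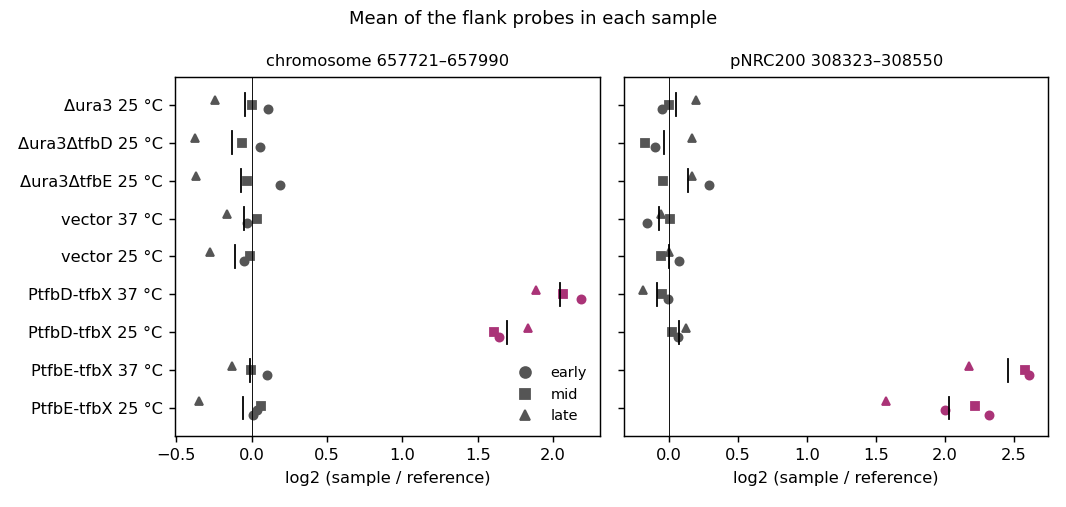
Mean log2 ratio of sample over reference (horizontal) of the raised probes at each of the 2 places, for every sample by group (vertical) and growth phase (markers), with a line at each group mean. Samples with PtfbD-tfbX lie at 1.61 to 2.18 on the chromosomal probes and samples with PtfbE-tfbX at 1.57 to 2.61 on the pNRC200 probes.

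To ask which transcripts depend on temperature, 25 °C was compared with 37 °C in each construct strain. The 5 genes at 22513 to 26184, present on both plasmids with shared sequence, were higher at 25 °C, at 2.18 ± 1.47 (SD, n = 3) against 0.32 ± 0.44 (n = 3) in the vector strain and 2.44 ± 0.98 against 1.02 ± 0.77 in the PtfbD-tfbX strain. In the PtfbE-tfbX strain the 3 genes at 22513 to 25008 of pNRC100 were higher by 1.57 on average. On the chromosome, the 3 genes at 1304143 to 1307982 fell by 0.47 in the vector strain and by 0.49 in the PtfbD-tfbX strain, and the 3 genes at 1897057 to 1899384 rose by 0.56 in the vector strain.

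In limma 165 genes were called in the vector strain, 63 higher and 102 lower at 25 °C, 72 in the PtfbD-tfbX strain (19 and 53) and 50 in the PtfbE-tfbX strain (18 and 32). In the vector strain VNG6029G of pNRC200 at 22513 to 22740 rose by 2.84 (SE 0.42; adjusted p 0.00213) and VNG7025, its copy on pNRC100, by 2.80 (SE 0.45; adjusted p 0.00213). VNG6269C at 208321 to 208716 of pNRC200 fell by 1.07 (SE 0.31; adjusted p 0.0456) and VNG0258H at 210631 to 210942 of the chromosome by 1.04 (SE 0.22; adjusted p 0.0135). In the PtfbD-tfbX strain VNG7025 rose by 2.13 (SE 0.45; adjusted p 0.0168) and VNG6268C at 206389 to 208296 of pNRC200 fell by 1.01 (SE 0.26; adjusted p 0.0383). In the PtfbE-tfbX strain VNG6029G rose by 2.06 (SE 0.40; adjusted p 0.0162), whereas VNG1240G at 932905 to 935064 of the chromosome fell from 1.29 ± 0.65 (n = 3) to 0.16 ± 0.12 (n = 4), with adjusted p 0.0394. No scan day held vector or PtfbD-tfbX samples of both temperatures, and with scan day as a fixed block 0, 0 and 11 genes were called in the vector, PtfbD-tfbX and PtfbE-tfbX strains, where the days of the 2 temperatures were linked through the PtfbE-tfbX samples alone. With that block VNG6029G was higher by 2.57 (SE 0.69; adjusted p 0.275) in the vector strain and by 2.45 (SE 0.47; adjusted p 0.0426) in the PtfbE-tfbX strain, and VNG7025 by 1.81 (SE 0.75; adjusted p 0.833) in the PtfbD-tfbX strain. In the PtfbE-tfbX strain VNG7025 was no longer called with that block (2.40, SE 0.52; adjusted p 0.0540), and with slide as a fixed block neither was VNG6029G (2.51, SE 0.59; adjusted p 0.243), where 2 genes were called in all. With scan day as a block, VNG6029G and VNG7025 in the vector and PtfbD-tfbX strains had a wider SE and a smaller difference than without it. VNG0258H in the vector strain instead fell by more, by 1.13 (SE 0.37). With slide as a block the difference of VNG7025 in the PtfbD-tfbX strain did not shrink, at 2.16 (SE 1.10). Leaving out single samples gave 16 to 224, 6 to 52 and 7 to 77 genes in the same order.

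The difference between temperatures was widest late in growth. In the vector strain 11 genes differed more than 2-fold between the early samples, 14 between the mid samples and 333 between the late samples. The PtfbD-tfbX strain gave 31, 12 and 148 and the PtfbE-tfbX strain 32, 28 and 120. These counts compare single samples and were not tested.

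Whether the constructs act differently at the 2 temperatures was tested as an interaction. For PtfbD-tfbX the 22 pNRC100 genes at 107101 to 132360 were lower at both temperatures, and limma called no gene for either construct. At an unadjusted p under 0.05 there were 19 genes for PtfbD-tfbX and 45 for PtfbE-tfbX. On simulated data the PtfbE-tfbX interaction recovered 83.5% of genes changed by a log2 of 1 and 39.0% of those changed by 0.5. Those data held independent noise and no slide, scan day or growth phase by temperature effects, so recovery in the real samples may be lower.

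The vector alone was tested by comparing the vector strain with the ΔtfbD strain at 25 °C. The chromosomal gene VNG1875G at 1386211 to 1387446 stood at 1.59 ± 0.05 (SD, n = 3) with the vector and -0.09 ± 0.79 (n = 3) without it. VNG0995H at 760369 to 760512 was higher by 1.18 (SE 0.21) and VNG1228C lower by -0.53 (SE 0.06). The 9 genes at 277999 to 286458 of pNRC200 stayed low with the vector, at -1.14 ± 0.12.

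In limma 13 genes were called, 12 higher and 1 lower, with adjusted p 0.00239 for VNG1875G, 0.00980 for VNG0995H and 0.000331 for VNG1228C. The groups share no scan day, and with scan day as a fixed block, as with slide, no gene was called in limma. Over the 13 genes the SE with scan day as a block was 1.67 to 2.03 times that without it (median 1.99), and the difference 0.788 to 1.64 times (median 1.18), smaller in 3 of them. With scan day as a block VNG1228C was lower by -0.53 (SE 0.13; adjusted p 0.165), VNG1875G higher by 1.32 (SE 0.46; adjusted p 0.411) and VNG0995H by 0.97 (SE 0.43; adjusted p 0.573), against 0.000331, 0.00239 and 0.00980 without it.

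Growth phase was tested over all groups as late against early. The 27 genes at 1258153 to 1275474 of the chromosome, 26 of them on the plus strand, fell by 1.71 on average. At 25 °C, over 6 strains, they went from 0.45 ± 0.08 (SD, n = 7) early to -1.76 ± 1.02 (n = 6) late, and at 37 °C, over 3 strains, from 0.25 ± 0.08 (n = 3) to -0.47 ± 0.06 (n = 3). The 12 chromosomal genes at 485185 to 497004 fell by 0.88. Late levels were higher for the 4 genes at 202147 to 205818 of pNRC200, by 3.44 on average, for the 14 genes at 186355 to 195192, by 1.37, and for the 6 chromosomal genes at 1825111 to 1830294, by 1.54.

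In limma 2012 genes were called, 981 higher and 1031 lower late, and 1205 of them had the same direction in all 9 groups. Of the called genes, 173 rose and 80 fell more than 2-fold. VNG6262G at 202147 to 203130 rose by 4.14 (SE 0.28; adjusted p 2.17e-09) and VNG6265G at 203911 to 204978 by 3.91 (SE 0.27; adjusted p 2.17e-09). VNG1691G at 1260841 to 1261068 fell by 2.02 (SE 0.31; adjusted p 1.82e-05) and VNG1706G at 1266469 to 1266612 by 2.0 (SE 0.34; adjusted p 4.49e-05). Within the scan days that held at least 2 early and 2 late samples 2091 and 1467 genes were called, and on the day that held 4 samples against 1 no gene was called.

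Whether the change late in growth differed between the temperatures was tested next. At 37 °C all early samples were read on 1 slide and scan day and all late samples on other slides on another day, so growth phase was separated from batch there only through the mid samples. A test of growth phase by temperature in limma called 1151 genes, 432 with a more positive and 719 with a more negative change at 25 °C. The Δura3, ΔtfbD and ΔtfbE strains were grown at 25 °C alone, and the same test in the 3 strains grown at both temperatures called 1240 genes, 466 more positive and 774 more negative. With scan day as a fixed block 57 genes were called over all strains and 155 in these 3, and with slide 3 and 4, while the median SE over all strains went from 0.124 to 0.237 with scan day and 0.252 with slide. Without a block, in these strains the SD of the late against early change over genes was 0.637 at 25 °C and 0.376 at 37 °C, with a correlation of 0.602 between them, and with scan day as a block 0.646 and 0.385. The 12 genes at 485185 to 497004 fell by 1.07 at 25 °C and by 0.24 at 37 °C in them, and the 27 genes at 1258153 to 1275474 by 1.30 and 0.73, whereas the 4 genes at 202147 to 205818 of pNRC200 rose by 2.59 and 3.25.

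**Figure D5:**
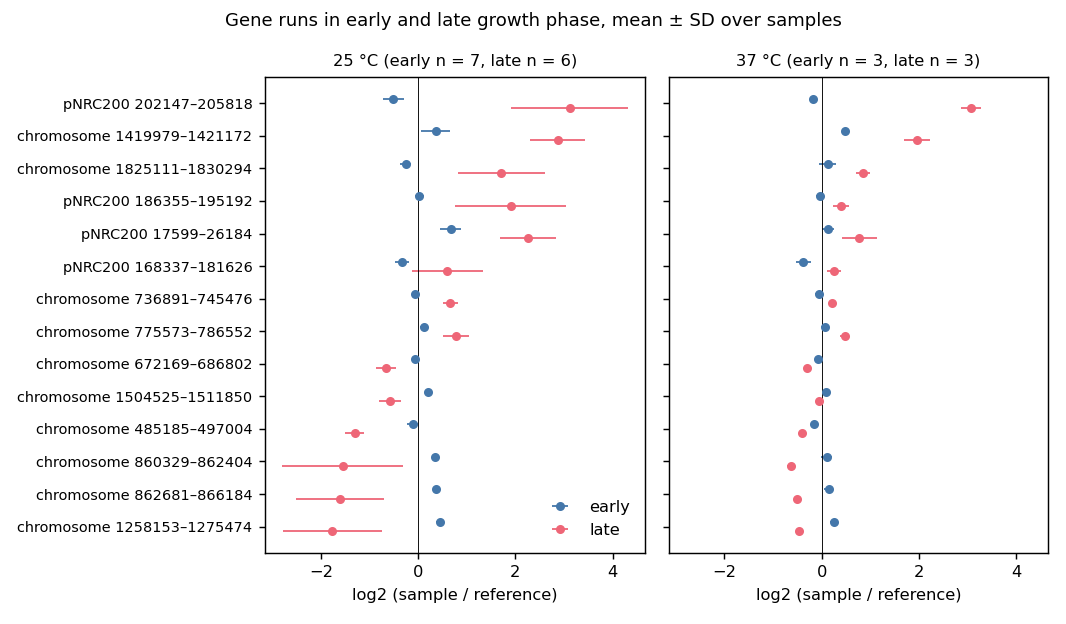
Mean log2 ratio of sample over reference (horizontal) of 14 gene runs (vertical) in early and late samples, mean ± SD, at 25 °C (n = 7 early, 6 late) and 37 °C (n = 3 and 3). The 25 °C panel pools 6 strains and the 37 °C panel the 3 with a vector or construct; in these 3 (n = 4 early and 3 late at 25 °C) the 27 genes at 1258153 to 1275474 of the chromosome fell by 1.30 at 25 °C and by 0.73 at 37 °C, where early and late samples were read on different scan days.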

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

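The tests of slide and scan batch, of probes outside gene strands, of the rest of pNRC100, of the promoter copies, of the weak array and of other splits of the samples were chosen after the results were seen, and those of the loss of DNA segments were written before their result was seen.

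Transcripts from 263929 to 307290 of pNRC200 were lower in every strain that lacks tfbD. A change of the genes alone is argued against by 289 probes outside gene strands. Within ends found from gene-strand probes alone, their median was -0.333 (quartiles -0.74 and -0.13). The 1030 such probes on the rest of pNRC200 had a median of -0.0887, which the bound of that test did not take into account, so the argument is weaker. A slide or scan batch is argued against by the comparison within slides, where the smaller difference was -0.61. Loss of this DNA from the ΔtfbD strain may be the cause: what remains would then be cross-hybridization and background, taken not to follow growth phase. In the groups without tfbD 68.1% to 89.1% of the readings lay above background, so background alone is not what remains, and cross-hybridization was not measured. The spread of the late minus early change in the ΔtfbD strains was 0.819 of that in the control strains. A loss needed at most 0.8 and each such strain below both controls. PtfbE-tfbX at 25 °C, at 0.809, lay above the Δura3 strain, at 0.744, so the test did not meet what a loss predicts. Short of its bound against a loss, the test left this open. The value of 0.809 rests on the late sample that holds the weakest array, and the test was not repeated without that array. The ΔtfbD, vector and PtfbD-tfbX strains at 25 °C, at 0.629, 0.504 and 0.639, lay below both controls. A loss of the DNA and a fall of transcription on both strands cannot be told apart from RNA, because no DNA was measured. If it is a loss, the genes called in this segment would not measure what tfbD does.

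Transcripts from 59851 to 164910 of pNRC100 were lower with PtfbD-tfbX at both temperatures, of which only 112771 to 154074 holds probes without a copy on pNRC200. A change of the genes alone is argued against by the 295 probes outside gene strands within ends found from gene-strand probes alone, at -0.71, a batch by the smaller difference within slides, -0.796, and a lower copy number of the whole plasmid by the rest of pNRC100, which stood at 0.0712. A loss of the segment in this strain may be the cause, and the spread of late minus early change was 0.366 of that in the other strains at 25 °C and 0.901 at 37 °C. A loss needed at most 0.8 at both temperatures, so the test left this open. At 25 °C the relative spread was 0.276 with PtfbD-tfbX, against 0.642 to 0.904 in the other strains. At 37 °C it was 0.32 against 0.352 and 0.359, already small in the other strains, so that temperature had little room to show a loss. A loss and a fall of transcription on both strands cannot be told apart for this segment. If it is a loss, the genes called there would not measure what tfbX does.

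Probes in or near VNG0870G rose by 1.81 at 25 °C and 2.1 at 37 °C in the PtfbD-tfbX strain, at 657721 to 657990 of the chromosome, and probes at 308323 to 308550 of pNRC200 by 2.02 and 2.52 in the PtfbE-tfbX strain. A candidate explanation is transcription from the promoter copy on the construct plasmid, which predicts a rise only in the strain with its own construct: the largest clusters of probes picked at 37 °C alone lay at these places, and in the samples at 25 °C the smaller gap between own and other strains was 1.03, while the largest clusters picked at 25 °C alone lay elsewhere, with gaps of -0.305 and -0.0874 at 37 °C. A batch is argued against by the rise within slides, which was at least 1.66. At 37 °C, single probes were also raised, at 656545 of the chromosome by 1.62 with PtfbD-tfbX and 2.32 with PtfbE-tfbX, and at 1504231 and 1504315 by 1.17 and 1.27 with PtfbD-tfbX, and for these no explanation was tested; the first rose with both constructs, which 1 promoter does not explain. The rise of VNG0870G is measured in part by the same probes.

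In the PtfbE-tfbX strain at 25 °C, replicate 4, the late sample, stood apart from the other 3 in 6 of 33 values. The gap was a share of 0.849 of the range for VNG6010G (-2.22 against -4.14 to -3.85), 0.83 for VNG0870G (-0.30 against 0.15 to 0.24) and 0.932 for VNG6176G (-0.12 against -0.20 to -0.19). It was 0.855 for VNG1534H (0.45 against -1.0 to -0.79), 0.877 for VNG1875G (0.75 against 1.5 to 1.6) and 0.874 for the raised probes of the chromosome (-0.35 against 0.01 to 0.06). Chance flags about 1 in 20 groups, and this sample holds 1 of the 2 weakest arrays and is the only late sample of its group. With the arrays that hold the sample in Cy3 alone, which leave the weak array out, the gap to the nearest other sample was 0.335 of its size for VNG6010G, 0 for VNG6176G and 0.432 for VNG1875G, so the weak array may have widened these. It was 0.842 for VNG0870G, 1.08 for VNG1534H and 0.934 for the raised probes of the chromosome, which argues against the weak array there. On those raised probes the late samples of the Δura3, ΔtfbD, ΔtfbE and vector strains at 25 °C also lay low, at -0.378 to -0.242, so growth phase remains open for that value. The genes whose late against early change differed between the temperatures numbered 1151 over all strains and 1240 in the 3 strains grown at both, a test chosen after the result was seen, but 57 and 155 with scan day as a fixed block and 3 and 4 with slide. Fewer genes were called as the median SE over all strains rose from 0.124 to 0.237 with scan day and 0.252 with slide. The SD of the change over genes at 25 °C and 37 °C stayed at 0.797 against 0.385 with scan day (0.803 against 0.376 without). At 37 °C early and late samples share no scan day, so a batch is not excluded.

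Other splits of the same samples were counted for each comparison. For groups of 3 against 3, the 10 splits cannot give a share under 0.05. The real split and the highest other called 69 and 0 genes for the ΔtfbD against the Δura3 strain, 7 and 0 for the ΔtfbE against the Δura3 strain, and 53 and 1 for the ΔtfbE against the ΔtfbD strain. They called 86 and 0 for PtfbD-tfbX against the vector at 25 °C, 103 and 0 at 37 °C, 4 and 0 for PtfbE-tfbX against the vector at 37 °C and 70 and 0 for PtfbE-tfbX against PtfbD-tfbX at 37 °C. For temperature they called 165 and 0 in the vector strain and 72 and 0 in the PtfbD-tfbX strain, and 13 and 0 for the vector against the ΔtfbD strain; in each of these 1 split, the real one, reached the count. With 35 splits, 1 split reached the 77 genes of PtfbE-tfbX against PtfbD-tfbX at 25 °C and 1 the 50 genes of temperature in the PtfbE-tfbX strain, a share under 0.05, but the highest others called 74 and 45, so the counts alone barely set the real groups apart. Chance is not excluded for PtfbE-tfbX against the vector at 25 °C, where 3 of 35 splits called at least 4 genes and the highest other called 41. For the interactions, any of the 100 splits reaches a real count of 0, so the share tests nothing there, and the highest others called 81 and 223 genes for PtfbD-tfbX and PtfbE-tfbX. Splits that call several times the real count point to a structure of the samples, which was not tested. For late against early growth 1 of 100 splits reached 2012, a share under 0.05, and the highest other called 1938, which is again close to the real count.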

How the results depend on the processing

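The growth phase by temperature term, the fit without the 2 weakest arrays, the fit with 1 gene kept of each shared sequence, the fit without the genes of the plasmid segments, and the blocks and the choice of strains in the test of growth phase by temperature were chosen after the data were seen. Values below are genes called where a setting moved the count by over 1.5 times, with the report's count in brackets at first mention. In 281 of the count results the call stayed within that bound, and 119 moved. Among the named genes 966 fits kept the call, 210 lost it with the direction kept, and none reversed. The cause was not tested, except where leaving genes out lowers a count by construction. The fixed gene lists were not run, because the files give no gene names.

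Without the growth phase term, the ΔtfbD against the Δura3 strain gave 35 genes (69), the ΔtfbE against the Δura3 strain 4 (7) and the ΔtfbE against the ΔtfbD strain 34 (53). PtfbD-tfbX against the vector gave 52 at 25 °C (86) and 58 at 37 °C (103), PtfbE-tfbX against PtfbD-tfbX at 25 °C 45 (77) and PtfbE-tfbX against the vector at 37 °C 0 (4; 33 at an unadjusted p under 0.05 in the limma fit of the report). For temperature there were 2 in the vector strain (165), 1 in the PtfbD-tfbX strain (72) and 1 in the PtfbE-tfbX strain (50), and 3 for the vector against the ΔtfbD strain (13).

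With the growth phase by temperature term there were 16 for the ΔtfbE against the Δura3 strain, 155 and 154 for temperature in the PtfbD-tfbX and PtfbE-tfbX strains and 33 for the vector against the ΔtfbD strain.

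With slide as a fixed block the knockout comparisons in the order above gave 34, 0 and 34 genes, PtfbE-tfbX at 37 °C 0 against the vector and 39 against PtfbD-tfbX (70), temperature 0 in the PtfbD-tfbX and 2 in the PtfbE-tfbX strain, and the vector against the ΔtfbD strain 0. This block was not available for the constructs against the vector at 25 °C, for temperature in the vector strain and for the interactions, since slides and groups coincide there. With scan day as a fixed block PtfbE-tfbX against the vector gave 41 at 25 °C (4) and 2 at 37 °C, temperature 0, 0 and 11 in the vector, PtfbD-tfbX and PtfbE-tfbX strains, and the vector against the ΔtfbD strain 0. As a random block, slide gave 66, 24 and 30 for temperature in these strains and scan day 21, 7 and 32, and scan day gave 5 for the vector against the ΔtfbD strain. The test of growth phase by temperature gave 57 with scan day and 3 with slide as a fixed block (1151).

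A fit of only the groups compared gave 1 for the ΔtfbE against the Δura3 strain, 23 for the ΔtfbE against the ΔtfbD strain, 37 and 0 for PtfbD-tfbX and PtfbE-tfbX against the vector at 25 °C, 391 and 75 for these at 37 °C, and 481 for PtfbE-tfbX against PtfbD-tfbX at 37 °C. It gave 0 and 6 for temperature in the vector and PtfbD-tfbX strains and 0 for the vector against the ΔtfbD strain.

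The authors' values gave 41, 4 and 35 for the knockout comparisons, 2 for PtfbE-tfbX against the vector at 25 °C and 0 at 37 °C, 50 for PtfbD-tfbX against the vector and 42 for PtfbE-tfbX against PtfbD-tfbX at 37 °C, 42, 29 and 13 for temperature, and 5 for the vector against the ΔtfbD strain. Without background subtraction PtfbE-tfbX against the vector gave 9 at 25 °C and 0 at 37 °C, and temperature 255 in the vector and 168 in the PtfbD-tfbX strain. Median centring gave 2 and 43 for PtfbE-tfbX at 37 °C against the vector and PtfbD-tfbX, 51 and 44 for temperature in the vector and PtfbD-tfbX strains, and 8 for the vector against the ΔtfbD strain.

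The arrays with the sample in Cy3 alone gave 2 for PtfbE-tfbX against the vector at 37 °C, 137 for temperature in the PtfbE-tfbX strain and 20 for the vector against the ΔtfbD strain. Those with the sample in Cy5 alone gave 2, 47, 16 and 15 for PtfbE-tfbX against the vector at 37 °C and for temperature in the vector, PtfbD-tfbX and PtfbE-tfbX strains, and 7 for the vector against the ΔtfbD strain. The scanner's processed signals gave 83 for temperature in the vector strain and 8 for the vector against the ΔtfbD strain, for which the median of a gene's probes gave 6. Without the 2 weakest arrays temperature gave 106 in the vector and 136 in the PtfbE-tfbX strain.

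Without the genes of the plasmid segments there were 33 for the ΔtfbD against the Δura3 strain, 17 for the ΔtfbE against the ΔtfbD strain, 9 and 7 for PtfbD-tfbX against the vector at 25 °C and 37 °C, 4 and 6 for PtfbE-tfbX against PtfbD-tfbX, and 8 for the vector against the ΔtfbD strain.

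Leaving out 1 sample gave 53 to 63, 6 to 10 and 41 to 50 genes in the knockout comparisons, 72 to 97 and 68 to 84 for PtfbD-tfbX against the vector at 25 °C and 37 °C, 3 to 43 and 2 to 3 for PtfbE-tfbX against the vector, and 57 to 106 and 46 to 56 for PtfbE-tfbX against PtfbD-tfbX. It gave 16 to 224, 6 to 52 and 7 to 77 for temperature, 0 to 0 for the interactions and 5 to 27 for the vector against the ΔtfbD strain. Late against early growth gave 1873 to 1994 when 1 group was left out and 1711 to 2039 over the other settings.

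PtfbE-tfbX against the vector at 25 °C gave 7 without vector replicate 2 and 43 without PtfbE-tfbX replicate 1. At 37 °C it gave 2 without vector replicate 1 or 2 or any PtfbE-tfbX replicate, PtfbD-tfbX against the vector gave 68 without vector replicate 2, and PtfbE-tfbX against PtfbD-tfbX gave 46 without PtfbE-tfbX replicate 1. Temperature in the vector strain gave 60, 100 and 16 without replicates 1, 2 and 3 at 37 °C and 17 without replicate 3 at 25 °C. In the PtfbD-tfbX strain it gave 6, 10 and 11 without replicates 1, 2 and 3 at 37 °C and 11 and 7 without replicates 1 and 3 at 25 °C. In the PtfbE-tfbX strain it gave 7, 8 and 7 without replicates 1, 2 and 3 at 37 °C, and 9, 8, 11 and 77 without replicates 1, 2, 3 and 4 at 25 °C. The vector against the ΔtfbD strain gave 6, 27 and 6 without vector replicates 1, 2 and 3, and 5, 6 and 6 without ΔtfbD replicates 1, 2 and 3.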

Other observations

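Against the wild-type reference, 4 genes lay below -1 in all 28 samples and none lay above 1. They stood at -1.51 ± 0.14 (SD, n = 28) for VNG0058H of the chromosome, -4.03 ± 0.46 for VNG6159H, read by 1 probe, and between these for the remaining genes of pNRC200. Over 310 to 335 kb of pNRC200, the median of 5-kb bins was -0.745 to -0.468 over the samples, and the highest of the 28 samples in any bin reached -0.214. These values set all strains against the reference, which differs from them in strain history, temperature or both, and were not tested.

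The vector strain held values of its own in the genes called for PtfbE-tfbX. VNG1228C stood at -0.43 ± 0.10 (SD, n = 3) with the vector at 25 °C and -0.30 ± 0.09 at 37 °C, while the means of all other groups lay from -0.01 to 0.17. VNG6177G stood at 0.23 ± 0.16 and 0.20 ± 0.09 with the vector, and in the other groups from -0.15 to -0.02.

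At 25 °C, the strains without a construct or vector had more genes over 2-fold late in growth than those with one. Late against early, 625, 650 and 666 genes differed more than 2-fold in the Δura3, ΔtfbD and ΔtfbE strains, 457, 297 and 200 in the vector, PtfbD-tfbX and PtfbE-tfbX strains at 25 °C, and 51, 86 and 66 in these at 37 °C. Each count rests on single samples, and the difference was not tested. The 200 of PtfbE-tfbX at 25 °C and the 51 of the vector strain at 37 °C rest in part on the 2 weakest arrays.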
